A study of Mus musculus with 8 samples.

How the data were processed

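Total RNA of low-density and high-density neutrophils from casein-elicited peritoneal cells was sequenced in 8 libraries, 2 for each combination of genotype (wild type or H2R deficient) and density. RNA was extracted with a Qiagen RNeasy kit and libraries followed Illumina's standard protocols, per the labels' protocols. The deposited values are raw read counts per gene, not normalized, in the layout that featureCounts writes, per the file headers. The submitters' processing notes name bcl2fastq 2.17.1.14, Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2 and the genome build GRCm38. The order and settings of those steps, the strand setting, the treatment of reads that map to several places, the annotation release and the sequencing instrument are not given in the sources used here. Without the strand setting, it is open to which of 2 overlapping genes on opposite strands a read was assigned, and genes with near-identical copies, such as ribosomal protein genes with their pseudogenes, globin genes and class II genes, may have lost or gained reads.

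The tables held 49315 gene identifiers, of which 48970 were matched to a symbol by identifier in the GENCODE M21 annotation and 345 were not. For 44823 identifiers the coordinates in the files equalled those of that annotation. Total counts ranged from 19862716 to 24199215 per library. At that depth a count of 0 allows a level of up to 0.124 to 0.151 CPM, taking a floor of 3 counts, and intervals of that kind cover counting error only because reads are not independent molecules. Libraries of a group differed beyond sampling noise, with a chi-square per degree of freedom of 33.7 to 53.5 over genes, and correlated at r = 0.973 to 0.980 across genes in log2 CPM, so no library was treated as a copy of another. Groups and replicate numbers were taken from the labels.

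Genes were kept with edgeR's filterByExpr by group, which left 14909, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 8 libraries (edgeR 4.0.16, R 4.3.3), leaving 4 residual degrees of freedom and a common biological coefficient of variation of 0.236. The contrasts were low against high density in each genotype, H2R deficient against wild type in each population, and the difference of the density effect between genotypes. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a contrast, and an adjusted p under 0.05 was called. Values in CPM are over TMM-scaled library sizes where a mean ± SD is given, and over all gene counts where single libraries, ranges over libraries or summed lists are given. Log2 fold changes carry a standard error from the fitted model. With 2 libraries per group no exact test of a single value could pass 0.05, so p-values come only from models fitted across all genes.

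Gene lists for neutrophil maturation, granules, inflammation, metabolism, stress and the histamine pathway, and marker lists of other cell types that a peritoneal preparation could hold, were fixed before the data were examined, as were the contrasts, the filters, the alternatives and the rule for naming genes. In each contrast 47 lists with at least 3 measured members were tested with limma's camera on voom-weighted log2 CPM (limma 3.58.1), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, were alternatives. The preset correlation called 28, 24, 16, 18 and 19 lists in the 5 contrasts in the order above, and the estimated correlation called 0 in each, with lowest adjusted p-values of 0.299, 0.430, 0.349, 0.447 and 0.524. Some genes stand in more than 1 list.

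Genes named are the 10 with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM in a compared group, groups that do not overlap, and a symbol that is not a predicted, clone, pseudogene, antigen receptor, mitochondrial or histone name. To these were added up to 4 members with the lowest adjusted p of each list discussed, Hrh2, and the detected members of the histamine list. Some of those genes are given by count only. Ighm, Ighd, Cr2, Fcer2a, Xist, Mpo, Elane, Ctsg, Ms4a3, Prtn3 and the Y-linked genes, given for their levels or as list members, were chosen after their values were seen.

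The tests were checked on simulated counts, drawn for the real genes from the real means, spread and library sizes with 200 changed genes. At a 4-fold change edgeR recovered 59.3% and 60.3% of planted genes for the density contrasts in wild-type and H2R-deficient libraries, 59.6% and 75.4% for the genotype contrasts in high-density and low-density libraries, and 26.8% for the difference of effects. At a 2-fold change it recovered 15% and 3.85%, 11.1% and 17.9%, and 1.20%. Its false calls were 11 of 55, 2 of 40, 5 of 48, 7 of 65 and 4 of 20, so the realised share of false calls was above 5% in these single runs, except that 2 of 40 equals it. DESeq2 1.42.0 made 33 false calls of 98, 22 of 91, 32 of 96, 25 of 105 and 18 of 52, and edgeR without the low-count filter made 72 of 144, 59 of 123, 64 of 135, 61 of 140 and 37 of 76. A planted list of 20 genes at a 2-fold change had adjusted p-values of at most 1.38e-06 with the preset correlation, and 0.0365, 0.0298, 0.354, 0.0248 and 0.180 with an estimated correlation. The preset correlation also called 2 lists that held no planted change in the high-density genotype contrast and 0 in the other 4. Each gene was drawn independently of the others, so the simulated lists held no genes that move together. These runs therefore cannot check the calls of real lists whose members vary together, as markers of a cell type may.

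Alternatives were other size factors, no scaling factors, other tools (DESeq2 and limma-voom), other filters on low counts, a fold threshold, leaving out mitochondrial, ribosomal protein and haemoglobin genes, fitting only the groups compared, blocking on the library number, and leaving out each library. The absence of scaling factors was chosen after the TMM factors were seen. Leaving out a library was first run with the gene filter applied again to the remaining libraries. After those values were seen, the filter was held at the 14909 genes so that only 1 choice changed, and both versions are given. The same holds for fitting only the groups compared. Leaving out both libraries of a number was chosen after Hrh2 in wild-type high-density library 2 was seen to stand apart, was run and dropped before its values were read, and was put back after other values were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and figures.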

Results

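Gene expression was measured by RNA sequencing in neutrophils of C57BL/6 mice, an inbred laboratory strain, aged 2 months. The cells were peritoneal neutrophils elicited with casein, a milk protein that draws neutrophils into the peritoneal cavity, and they were separated into a low-density and a high-density population. The mice were wild type or lacked the histamine H2 receptor (H2R), a receptor that couples to Gs and raises cyclic AMP. The 8 libraries formed 4 groups of 2. The wild-type libraries carried the numbers 2 and 4 and the H2R-deficient libraries the numbers 1 and 2. Each library held between 19862716 and 24199215 counts assigned to genes. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

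Transcripts of the targeted gene, Hrh2, were present in all libraries, with lower group means in H2R-deficient cells. Hrh2 (ENSMUSG00000034987) lies on chromosome 13 between 54192129 and 54236180 on the plus strand of GRCm38. Wild-type high-density libraries held 2003 and 700 Hrh2 counts (91.7 and 33.3 CPM over all gene counts), and wild-type low-density libraries held 556 and 830 (28 and 36.2 CPM). H2R-deficient high-density libraries held 599 and 275 counts (27 and 13 CPM), and H2R-deficient low-density libraries held 435 and 215 (18 and 10.2 CPM). The difference between genotypes was a log2 fold change of -1.60 ± 0.55 (SE) in the high-density and -1.48 ± 0.55 in the low-density population, and neither passed the test (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.192 and 0.196). The high-density difference of Hrh2 was -0.65 without wild-type high-density library 2 and -2.17 without library 4. It was -2.18 without H2R-deficient high-density library 1 and -1.19 without library 2. DESeq2 called Hrh2 lower at high and at low density (DESeq2 adjusted p = 0.0152 and 0.0270), but made more false calls than edgeR in simulated counts. Limma-voom did not call Hrh2 (limma-voom adjusted p = 0.212 and 0.127). Over TMM-scaled library sizes H2R-deficient high-density library 1 lay at 35.0 CPM of Hrh2, above both wild-type low-density libraries (22.5 and 32.5 CPM), so the genotypes overlapped across populations. The counts cover the whole gene, and the deleted part is not given in the sources used here, so reads from outside it may be included and the level checks the genotype only in part.

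Hdc, the enzyme that makes histamine, was among the more abundant transcripts, at 1820 to 5188 CPM in the 8 libraries. It fell with low density in H2R-deficient cells, from 5360 ± 924 to 1627 ± 575 CPM over TMM-scaled library sizes (mean ± SD, n = 2; log2 fold change -1.72 ± 0.31, edgeR adjusted p = 0.00195). In wild-type cells the Hdc change was -0.96 ± 0.31 and did not pass (edgeR adjusted p = 0.0670), but it passed in a fit with the library number as a replicate block (-0.99, edgeR adjusted p = 0.0194). That fit also called Hrh2 lower with low density in wild-type and H2R-deficient cells (edgeR adjusted p = 0.0362 and 0.0105), where the fit without the block did not (edgeR adjusted p = 0.0984 and 0.0631). Without the block the wild-type Hrh2 change was -1.53, and it was -0.59 without high-density library 2 and -2.10 without library 4. With total counts only the Hrh2 changes were -0.96 in wild-type and -0.50 in H2R-deficient cells and did not pass (edgeR adjusted p = 0.197 and 0.468). Without the block, the difference between the Hdc changes of the genotypes did not pass (-0.76 ± 0.43, edgeR adjusted p = 0.338). That between the Hrh2 changes was 0.12 (edgeR adjusted p = 0.950). Hnmt, which inactivates histamine by methylation, also fell in the low-density H2R-deficient cells (-1.27 ± 0.25). With total counts only the change of Hdc was -0.83 (edgeR adjusted p = 0.0167) and those of Hnmt (-0.36) and of the transporter Slc18a2 (-0.39) did not pass (edgeR adjusted p = 0.283 and 0.262). Mature neutrophil genes had medians near the Hdc changes, at -1.58 after TMM scaling and -0.69 with total counts only in H2R-deficient libraries. In wild-type libraries their median after TMM scaling was -0.85. Whether Hdc fell more than neutrophil genes in general was not tested. Of the 5 measured genes of the histamine list, 3 fell after TMM scaling, the third being Slc18a2 (-1.29 ± 0.26), and Aldh7a1 rose (1.51 ± 0.42), with 4 and 1 adjusted over the list alone. Of the 3 falls only that of Hdc passed with total counts only, and the rise of Aldh7a1 did not pass without H2R-deficient high-density library 2 or low-density library 1 (edgeR adjusted p = 0.0833 and 0.0825). Camera did not call this list (adjusted p = 0.107, and adjusted p = 0.457 with an estimated correlation), and its median moved from -1.29 to -0.39 with total counts only. Hrh1 had between 1 and 8 counts per library and Hrh4 between 1 and 10, against a floor of 3 counts.

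**Figure D1:**
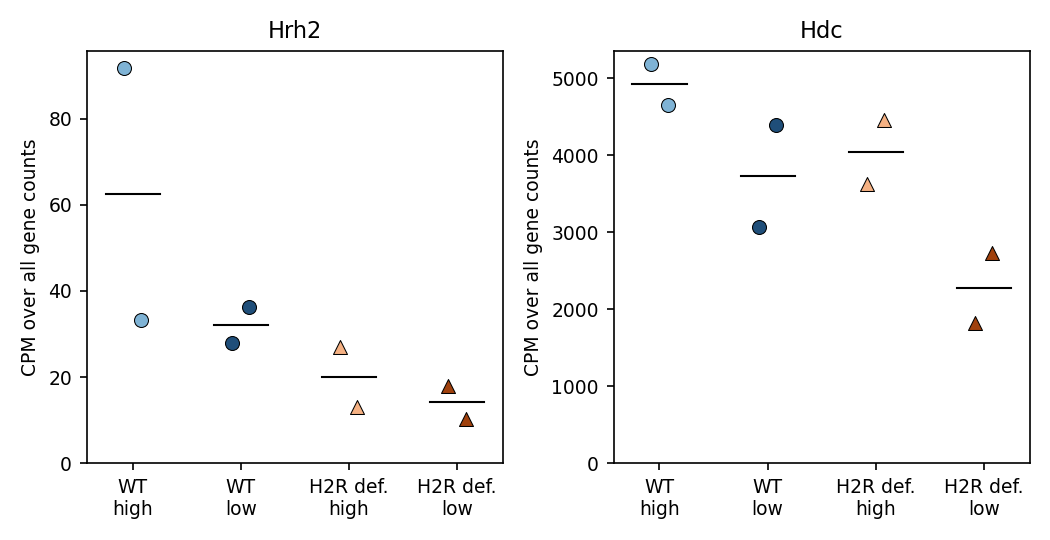
CPM of Hrh2 (left) and Hdc (right) in each of the 8 libraries, over all gene counts. Points are libraries, horizontal lines are group means of 2 libraries. Hrh2 was highest in 1 wild-type high-density library (91.7 CPM) and lay between 10.2 and 36.2 CPM in the other 7 libraries.

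Density separated the libraries more than genotype did. The first principal component of log2 CPM carried 67.0% of the variance and placed the 4 high-density libraries between -87.4 and -40.5 and the 4 low-density libraries between 46.0 and 104. The second carried 10.5%. The TMM factors followed the same division, at 0.742 to 0.808 in high-density libraries and 1.11 to 1.49 in low-density libraries. Without these factors the median log2 fold change of all tested genes between low and high density moved from 0.10 to 0.67 in wild-type and from 0.10 to 1.0 in H2R-deficient libraries, so directions between the populations are given relative to that shift.

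**Figure D2:**
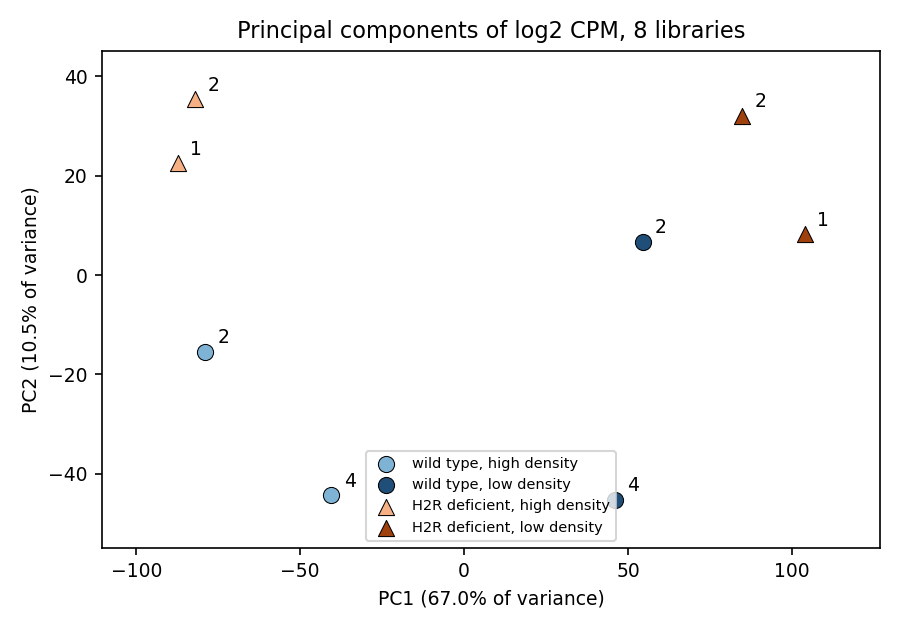
First and second principal components of log2 CPM for the 8 libraries, with the percent of variance on each axis. Symbols give genotype and colours give group, and the number beside a point is the library's number. All 4 high-density libraries lie below 0 on the first component and all 4 low-density libraries above it.

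The wild-type comparison asked how low-density neutrophils differed from high-density neutrophils. The low-density libraries held more transcripts of B cells, dendritic cells, NK cells and dividing cells and fewer transcripts of some mature neutrophil genes and of some NF-κB targets and immediate-early and dissociation stress genes. B cell markers were up by a median log2 fold change of 2.25, dendritic cell markers by 2.33 and proliferation genes by 2.26, while mature neutrophil genes had a median of -0.85. Of 14909 genes tested, 1888 passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, with 1269 higher and 619 lower in the low-density population.

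Of 14 measured B cell markers, 10 rose and 0 fell in wild-type low-density libraries (12 and 0 adjusted over the list alone). Ms4a1, which encodes CD20, rose from 10.2 ± 0.471 to 48.3 ± 23.8 CPM (SD, n = 2; log2 fold change 2.25 ± 0.33, edgeR adjusted p = 0.00886), and Blk, a B cell kinase, rose from 2.21 ± 0.712 to 17.9 ± 5.48 CPM. Of 10 dendritic cell markers, 6 rose and 0 fell (8 and 0 adjusted over the list alone). They included Flt3, the receptor for a dendritic cell growth factor (log2 fold change 4.68 ± 0.56), and Fscn1, an actin-bundling protein of mature dendritic cells, which went from 3.13 ± 3.42 to 141 ± 77.0 CPM (5.50 ± 0.86). In the MHC class II list 9 of 10 genes rose and 0 fell (9 and 0 adjusted over the list alone), among them H2-Ab1 at 1.40 ± 0.29 and the class II transactivator Ciita at 2.37 ± 0.32. Of 12 NK cell markers, 5 rose and 0 fell (9 and 0 adjusted over the list alone). Cxcr6, Icos and Cd163l1, a scavenger receptor, were among the 10 largest rises. Cd163l1 went from 2 to 8 counts in the high-density libraries of either genotype to 478 to 1195 counts in the low-density libraries.

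Proliferation genes rose in 28 of 40 cases and fell in 0 (31 and 0 adjusted over the list alone). Top2a, the topoisomerase of replicating cells, rose from 2.71 ± 1.25 to 22.8 ± 5.65 CPM (log2 fold change 3.07 ± 0.41), and the replication helicase subunit Mcm6 rose by 2.74 ± 0.34. Cytosolic ribosomal protein genes rose in 18 of 77 cases and fell in 1 (33 and 1 adjusted over the list alone), with Rpl10a at 1.28 ± 0.21. With total counts only, 71 of them rose and 0 fell. Their median moved from 0.48 to 1.06, while that of all tested genes moved from 0.10 to 0.67. For the B cell, dendritic cell, MHC class II, NK cell, proliferation and ribosomal protein lists, camera with a preset correlation gave adjusted p-values of at most 0.000391. With an estimated correlation their adjusted p-values lay between 0.335 and 0.565.

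Among mature neutrophil genes, 8 of 23 fell and 0 rose in wild-type low-density libraries (20 and 0 adjusted over the list alone). Il1r2, the decoy receptor for interleukin 1, fell from 2379 ± 197 to 1024 ± 325 CPM (log2 fold change -1.22 ± 0.26), and Mxd1, a MAX-binding repressor, fell from 7320 ± 985 to 3998 ± 572 CPM (-0.87 ± 0.20). Of 24 NF-κB targets and regulators, 11 fell and 0 rose (19 and 0 adjusted over the list alone), including Ptgs2, the inducible cyclooxygenase (-1.79 ± 0.26), and Ier3 (-1.44 ± 0.22). Immediate-early and dissociation stress genes, which respond to cell handling as well as to stimulation, fell in 9 of 24 cases and rose in 1 (13 and 1 adjusted over the list alone). Dusp1, a MAP kinase phosphatase, fell from 4762 ± 715 to 1665 ± 106 CPM (-1.52 ± 0.20), and Fos fell by 2.64 ± 0.59. The cyclic AMP list holds responsive genes and components of the pathway. Of its 28 measured members 8 fell and 2 rose (11 and 4 adjusted over the list alone). Nr4a1 was at -1.48 ± 0.25 and the phosphodiesterase Pde4b at -1.14 ± 0.21. Of 24 cytokine and chemokine genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone). Il1b fell by 1.65 ± 0.31 and Cxcl2 from 20903 ± 1696 to 9013 ± 720 CPM, while Ccl5, a chemokine of lymphocytes, rose by 3.02 ± 0.41. Camera with the preset correlation placed these 5 lists below other genes at adjusted p-values of at most 0.00109, and with an estimated correlation at adjusted p = 0.299 to 0.342.

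The sign of the medians of the cyclic AMP and the cytokine lists depended on the scaling. With total counts only the medians of these lists moved from -0.47 to 0.10 and from -0.47 to 0.09, while the medians stayed below 0 for mature neutrophil genes (-0.85 to -0.29), NF-κB targets (-0.67 to -0.10) and immediate-early genes (-1.17 to -0.61). Most calls of mature neutrophil genes and NF-κB targets were lost all the same, with 1 mature neutrophil gene and 2 NF-κB targets passing as lower and 0 as higher without TMM factors, against 8 and 11 with them, while 7 immediate-early genes passed as lower and 2 as higher. In the cyclic AMP list 5 genes still passed as lower, and 6 passed as higher. In the cytokine list 4 genes still passed as lower, and 2 passed as higher. The number of genes called also depended on single libraries. It was 93 without wild-type high-density library 2, 168 without low-density library 2, 788 without low-density library 4, 1158 without H2R-deficient low-density library 1 and 1117 without H2R-deficient low-density library 2. It was 581 when the 4 wild-type libraries were fitted alone. Without TMM factors 4946 genes passed, 4822 of them higher and 124 lower.

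Markers of erythroid cells and eosinophils went the other way. Of 6 erythroid genes 5 fell in wild-type low-density libraries and 0 rose (5 and 0 adjusted over the list alone). The globin gene Hbb-bs had 249 to 2052 counts in the 4 high-density libraries and 1 to 20 in the 4 low-density libraries. Of 8 eosinophil markers 4 fell and 1 rose (6 and 1 adjusted over the list alone), with Siglecf falling from 35.7 ± 4.29 to 17.5 ± 1.94 CPM. Camera gave adjusted p = 0.00109 and 0.000725 for these 2 lists with the preset correlation and adjusted p = 0.352 and 0.342 with an estimated correlation. Macrophage markers were called in 0 of 17 cases, with a median of 0.17.

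**Figure D3:**
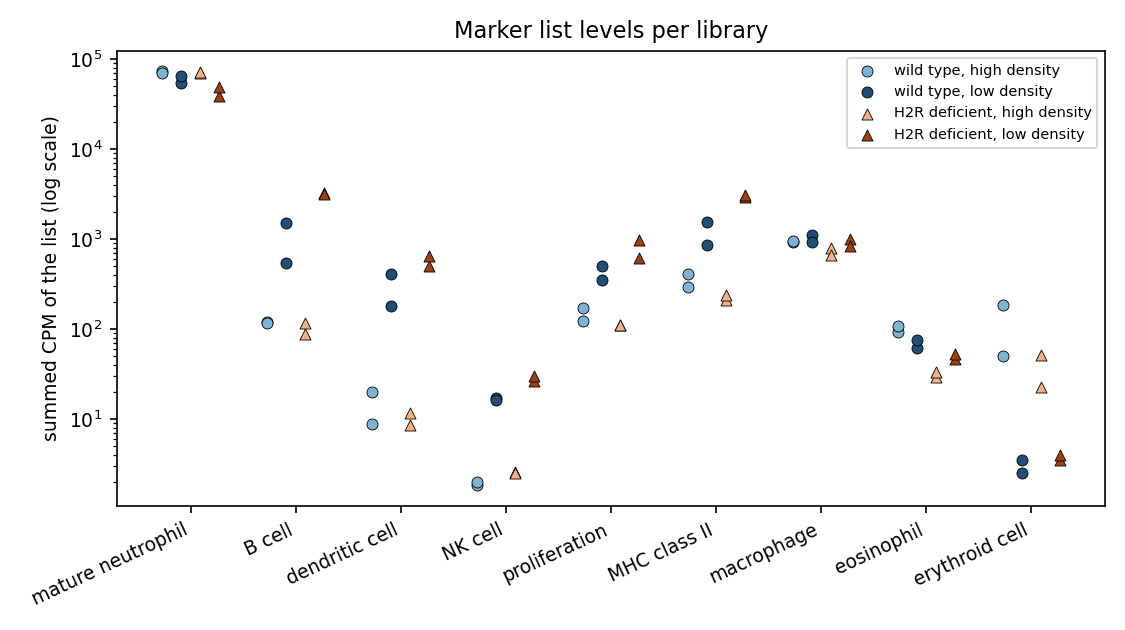
Summed CPM of the members of 9 gene lists in each library, on a log scale, with 1 point per library coloured by group. The B cell list sums to between 87.2 and 119 CPM in the 4 high-density libraries and between 545 and 3239 CPM in the 4 low-density libraries, while the macrophage list lies between 667 and 1126 CPM in all 8.

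In H2R-deficient mice the same comparison gave more calls, with a median absolute log2 fold change over all genes of 0.99 against 0.53 in wild type. Low-density libraries again held more transcripts of B cells, dendritic cells, class II presentation, protein synthesis and cell division, and, after TMM scaling, fewer of mature neutrophils, specific and gelatinase granules, interferon-stimulated genes and glycolysis. B cell markers were up by a median log2 fold change of 3.84 and mature neutrophil genes had a median of -1.58. Of 14909 genes, 8044 passed the edgeR test, 4478 higher and 3566 lower.

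Of 14 B cell markers 12 rose and 0 fell (12 and 0 adjusted over the list alone), with Ms4a1 going from 9.86 ± 2.30 to 149 ± 16.6 CPM (log2 fold change 3.92 ± 0.35, edgeR adjusted p = 0.000203) and Cd79a, a signalling chain of the B cell receptor, from 7.46 ± 1.72 to 125 ± 11 CPM. All 10 MHC class II genes rose (10 adjusted over the list alone), with H2-Ab1 at 3.39 ± 0.31. Dendritic cell markers rose in 7 of 10 cases and fell in 0 (7 and 0 adjusted over the list alone). Fscn1 rose from 1.48 ± 0.382 to 227 ± 63.9 CPM, and Ccl22, a chemokine of dendritic cells, from 3.58 ± 0.354 to 199 ± 53.2 CPM. Proliferation genes rose in 36 of 40 cases and fell in 0 (36 and 0 adjusted over the list alone), with Mcm6 at 3.88 ± 0.35. Cytosolic ribosomal protein genes rose in 74 of 77 cases and fell in 0 (74 and 0 adjusted over the list alone), with Rpl10a at 2.80 ± 0.22. Nuclear genes of oxidative phosphorylation rose in 41 of 76 cases and fell in 1 (41 and 2 adjusted over the list alone), among them the complex I subunit Ndufa9 at 2.12 ± 0.22. With total counts only, 74 of these nuclear genes rose and 0 fell. Their median moved from 0.57 to 1.48, while that of all tested genes moved from 0.10 to 1.0. Camera with the preset correlation gave adjusted p-values of at most 0.0156 for these 6 lists, and with an estimated correlation adjusted p = 0.457 to 0.470. The mitochondrially encoded list, a mark of library quality too, had a median of 0.63 with 0 of 10 members called (0 adjusted over the list alone; camera adjusted p = 0.193, and adjusted p = 0.759 with an estimated correlation), and a median of 1.53 with 9 called higher without TMM factors. Mitochondrial genes held 0.311% and 0.159% of counts in the H2R-deficient high-density and 0.590% in both low-density libraries.

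All 23 mature neutrophil genes fell in H2R-deficient low-density libraries (23 adjusted over the list alone). The chemokine receptor Cxcr2 fell from 2590 ± 69.1 to 717 ± 185 CPM (log2 fold change -1.85 ± 0.25, edgeR adjusted p = 0.000535), and Mxd1 fell from 8483 ± 93.4 to 2681 ± 253 CPM. Of 15 specific granule genes 10 fell and 0 rose (10 and 0 adjusted over the list alone), with the collagenase Mmp8 falling from 3478 ± 161 to 1214 ± 283 CPM. Primary granule genes had a median of 0.48, with 1 of 6 higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.933, and adjusted p = 0.957 with an estimated correlation), and of 1.36 without TMM factors. Gelatinase granule and secretory vesicle genes fell in 11 of 13 cases and rose in 2 (11 and 2 adjusted over the list alone), with Itgam, the CD11b integrin chain, at -1.31 ± 0.19. Type I interferon-stimulated genes fell in 26 of 36 cases and rose in 2 (29 and 3 adjusted over the list alone), with Slfn4 falling from 18299 ± 2212 to 5495 ± 2268 CPM. NF-κB targets fell in 21 of 24 cases and rose in 0 (22 and 0 adjusted over the list alone). Glycolysis genes fell in 17 of 21 cases and rose in 0 (17 and 0 adjusted over the list alone), with the hexokinase Hk3 at -1.22 ± 0.17 and the glucose transporter Slc2a1 at -1.45 ± 0.21. Camera with the preset correlation gave adjusted p-values of at most 0.000683 for these 6 lists, and with an estimated correlation adjusted p = 0.430 to 0.496.

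With total counts only, the medians of these 6 falling lists stayed below 0, at -0.69 for mature neutrophil, -0.45 for specific granule, -0.38 for gelatinase and secretory vesicle, -0.61 for interferon-stimulated, -0.02 for NF-κB and -0.05 for glycolysis genes. Without TMM factors 15 mature neutrophil genes passed as lower and 0 as higher, but the other lists lost most calls, with 3 lower and 1 higher for specific granule, 3 and 2 for gelatinase and secretory vesicle, 8 and 3 for interferon-stimulated, 1 and 1 for NF-κB and 3 and 2 for glycolysis genes. The fall of those 5 lists therefore depended on the scaling. The cyclic AMP list had a median of -0.46 in H2R-deficient libraries, against -0.47 in wild type, and of 0.45 with total counts only. Between genotypes its median was -0.215 at high and -0.064 at low density. Autophagy genes, of which 17 of 29 fell and 2 rose (17 and 2 adjusted over the list alone; camera adjusted p = 0.000144, and adjusted p = 0.430 with an estimated correlation), had a median of -0.73 that moved to 0.17, and lysosome genes, of which 17 of 31 fell and 3 rose (17 and 4 adjusted over the list alone; camera adjusted p = 0.00134, and adjusted p = 0.470 with an estimated correlation), had a median of -0.67 that moved to 0.24. Inflammatory cytokines went both ways after TMM scaling, with 6 of 24 higher and 7 lower (6 and 7 adjusted over the list alone). Ccl2 rose by 1.61 ± 0.17 and Il1b fell by 1.67 ± 0.31. With total counts only, 11 cytokine genes passed as higher and 1 as lower, and the list's median moved from -0.10 to 0.81. The unfolded protein response genes Pdia4 (3.26 ± 0.21) and Sdf2l1 (3.0 ± 0.28), which act in the endoplasmic reticulum, were among 8 of 25 members that rose after TMM scaling, and 5 fell (8 and 5 adjusted over the list alone). For this list 15 members passed as higher and 1 as lower with total counts only, and the median moved from -0.09 to 0.82. Without TMM factors 8077 genes passed, 7690 higher and 387 lower.

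**Figure D4:**
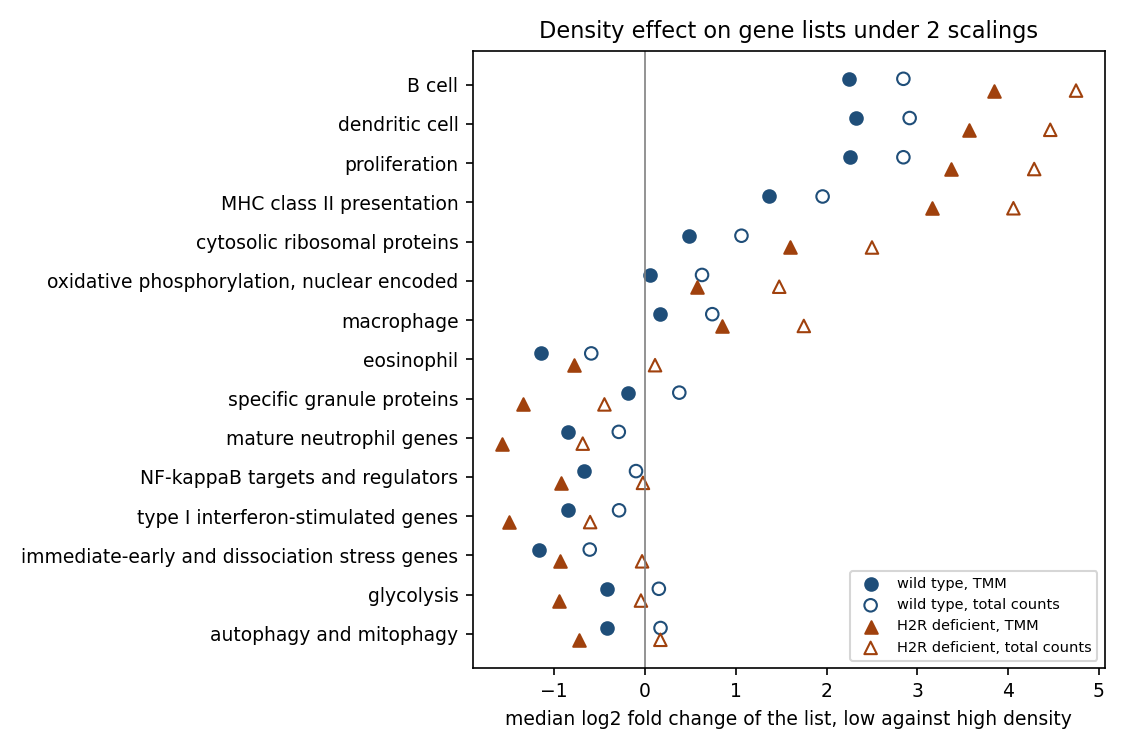
Median log2 fold change of 15 gene lists, low against high density, in wild-type (circles) and H2R-deficient (triangles) libraries, after TMM scaling (filled) and with total counts only (open). Every list moves up without TMM factors, and the medians of autophagy genes cross 0 in both genotypes and those of glycolysis and specific granule genes cross 0 in wild type only and that of eosinophil markers in H2R-deficient libraries only.

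The density effects of the genotypes went the same way for most genes. Across the 14909 genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.785 and a Spearman correlation of 0.814. No library entered both comparisons. In both genotypes 1210 genes were higher in low-density libraries, against 381 for independent lists, and 555 were lower, against 148. Of the 1888 genes called in wild type, 99.4% had the same sign in H2R-deficient cells, and 1 gene was called in opposite directions.

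The comparison of high-density neutrophils between genotypes asked what the receptor's absence changed in that population. A few genes typical of macrophages and eosinophils were lower in H2R-deficient high-density libraries, while most members of their lists did not pass. Fn1, the extracellular matrix protein fibronectin, went from 675 ± 32.7 to 147 ± 50.2 CPM. Of 14909 genes 31 passed the edgeR test, 28 lower and 3 higher in H2R-deficient cells.

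Fn1 fell by 2.20 ± 0.25 on the log2 scale (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0374). Ace, which encodes angiotensin-converting enzyme (-2.36 ± 0.29), the adhesion receptors Itgb8 (-2.13 ± 0.30) and Itga4 (-1.38 ± 0.20), the adhesion G protein-coupled receptor Adgre4 (-2.05 ± 0.28), the lipid carrier Apoe (-1.48 ± 0.19) and the eosinophil lectin Siglecf (-1.41 ± 0.21) also fell. Among the 3 genes that rose was Styk1 (3.02 ± 0.45). Of 17 macrophage markers 2 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -1.48. The mannose receptor Mrc1 (-1.84 ± 0.29, edgeR adjusted p = 0.0509) and C1qb (-1.82 ± 0.30, edgeR adjusted p = 0.0550) did not pass. Of 8 eosinophil markers 1 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -1.65. Camera placed both lists below other genes with the preset correlation (adjusted p = 1.01e-07 and 3.28e-07), and gave adjusted p = 0.349 for both with an estimated correlation. The monocyte list had a median of -1.20 with 0 of 12 members called (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00197, and adjusted p = 0.399 with an estimated correlation). Summed over its members the monocyte list differed little, at 428 and 514 CPM in H2R-deficient and 537 and 500 CPM in wild-type high-density libraries, and the macrophage list was at 799 and 667 against 931 and 953 CPM, the eosinophil list at 29.0 and 33.4 against 92.0 and 107 CPM. Among the 16 lists that camera called here with the preset correlation, T cell (median 1.99, camera adjusted p = 0.00197) and mast cell markers (1.30, 0.00122) were above other genes, and erythroid (-1.58, 0.00922) and ribosomal protein genes (-0.35, 9.77e-14) below them. With an estimated correlation these 4 lists had adjusted p = 0.758, 0.606, 0.735 and 0.735, and 0 of their members passed on their own (5 T cell markers rose adjusted over the list alone, and 0 members of the other 3 lists passed). The T cell list summed to 54.1 CPM in H2R-deficient high-density library 2 and to 13.6 CPM in library 1, below the 15.7 and 20.6 CPM of the wild-type libraries.

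Specific granule genes had a median of 0.59 in H2R-deficient high-density libraries, and 0 of 15 members passed (4 rose and 0 fell adjusted over the list alone). Ltf, the granule protein lactoferrin, was at 396 ± 164 against 105 ± 34.8 CPM (log2 fold change 1.92 ± 0.38, edgeR adjusted p = 0.0869), and the neutrophil surface protein Cd177 was at 1268 ± 98.4 against 563 ± 159 CPM (1.17 ± 0.32). Camera gave this list adjusted p = 0.000663 with the preset correlation and adjusted p = 0.735 with an estimated correlation. The 31 calls rested on several libraries and on the model. They became 0 without H2R-deficient high-density library 2, without either H2R-deficient low-density library or without either wild-type low-density library, 1 without H2R-deficient high-density library 1, 8 without wild-type high-density library 4, 34 without wild-type high-density library 2 (11 of them among the 31), and 0 when the 4 high-density libraries were fitted alone. DESeq2 called 699 genes, limma-voom 2, and edgeR without factors 73.

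By list medians, B cell, class II and ribosomal protein genes lay higher and mature neutrophil and macrophage genes lower in H2R-deficient than in wild-type low-density libraries. Camera called these 5 lists only with the preset correlation (adjusted p = 0.447 for each with an estimated correlation), and fry called 0 lists. B cell markers had a median log2 fold change of 1.42 and class II genes of 1.07, and mature neutrophil genes had a median of -0.68. In low-density neutrophils 0 genes passed the edgeR test between the genotypes, with 3128 at an unadjusted p under 0.05 where 745 would be expected with no effect. DESeq2 called 915 genes (387 higher and 528 lower) and limma-voom 0.

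Over the lists alone, 12 of 14 B cell markers, 9 of 10 class II genes and 73 of 77 ribosomal protein genes passed as higher, and 15 of 23 mature neutrophil genes and 6 of 17 macrophage markers as lower, although 0 passed over all genes (those counts are adjusted over the list alone). Ms4a1 was at 149 ± 16.6 against 48.3 ± 23.8 CPM in wild type (log2 fold change 1.63 ± 0.32), Rpl10a at 139 ± 8.50 against 70.4 ± 11.6 CPM (0.98 ± 0.21) and Il1r2 at 384 ± 97.2 against 1024 ± 325 CPM (-1.41 ± 0.26), each at an edgeR adjusted p of 0.104. The lowest adjusted p over all genes was 0.0868, shared by the integrin Itgax (-1.29 ± 0.17) and the interferon-induced GTPase Gbp3 (1.36 ± 0.19). Camera with the preset correlation gave these 5 lists adjusted p-values of at most 8.5e-06, and with an estimated correlation each had adjusted p = 0.447. With total counts only the median of all genes moved from 0.05 to 0.32 and these medians kept their signs, at 1.65, 1.32 and 1.03 for the B cell, class II and ribosomal protein lists and -0.41 and -0.38 for the mature neutrophil and macrophage lists. Mitochondrially encoded genes, a mark of library quality as well as of metabolism, also had a higher median in H2R-deficient low-density libraries (0.63, with 0 of 10 called and 0 adjusted over the list alone; camera adjusted p = 0.0190, and adjusted p = 0.573 with an estimated correlation). Mitochondrial genes held 0.590% of counts in both of these libraries against 0.387% and 0.284% in wild type. Without wild-type low-density library 2 the count of called genes became 63, and without either wild-type high-density library it became 2.

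The difference of the density effect between genotypes was tested as an interaction. The rise of B cell, class II, proliferation and ribosomal protein transcripts with low density was larger in the H2R-deficient libraries by the medians of these lists. Mature neutrophil genes had a more negative median there, and so had specific granule genes, at -1.35 against -0.19 in wild type, where 0 of 15 were called (camera adjusted p = 0.346, and adjusted p = 0.782 with an estimated correlation). Camera called these 6 lists only with the preset correlation (adjusted p of 0.524 or more with an estimated correlation). For single genes 0 passed the edgeR test, with 3150 at an unadjusted p under 0.05 where 745 would be expected with no effect and a lowest adjusted p of 0.0906. DESeq2 called 990 genes (606 positive and 384 negative), limma-voom 0, and edgeR without TMM factors 635 (622 positive and 13 negative), among them 69 ribosomal protein and 8 class II genes, all positive. H2-Ab1 had a difference of 1.99 ± 0.41 (edgeR adjusted p = 0.0906), Fn1 of 1.48 ± 0.34 and Ms4a1 of 1.67 ± 0.46.

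The medians of the differences were 1.47 for B cell markers, 1.81 for class II genes, 1.13 for proliferation and 1.17 for ribosomal protein genes, and -1.02 for specific granule and -0.76 for mature neutrophil genes. With total counts only the median of all genes moved from 0.04 to 0.38, and the 6 list medians kept their signs, with -0.68 for specific granule and -0.43 for mature neutrophil genes. Adjusted over the list alone, 7 of 14, 9 of 10, 6 of 40 and 75 of 77 members were positive in the first 4 lists, 8 of 15 specific granule genes were negative and 0 of 23 mature neutrophil genes passed. Camera with the preset correlation gave adjusted p-values of at most 0.000245 for the 6 lists, and with an estimated correlation they ranged from 0.524 to 0.727. The self-test on simulated counts recovered 26.8% of genes given a 4-fold difference of effects and 1.20% of those given a 2-fold difference, so the count of 0 does not exclude differences of this size. Without wild-type high-density library 2 or another single library the count of calls stayed between 0 and 3, while a fit with the library number as a replicate block called 28 genes (12 positive and 16 negative).

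The genotype effects of the populations were barely related across genes, with Pearson r = 0.0529 and a Spearman correlation of -0.0183 over 14909 genes. The median absolute log2 fold change was 0.39 at high and 0.40 at low density. Noise between 2 libraries per group pulls such a correlation toward 0. The low value therefore does not show that the true effects differ between the populations. Of the 31 genes called in high-density libraries, 67.7% had the same sign in low-density libraries.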

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

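The list tests of the difference of the density effect between genotypes were planned, and all tests of explanations here were chosen only after the result was seen. The dilution test below was first made once over both genotypes and was split by genotype after its result was seen. A looser condition on medians, tried at the split, would have counted the H2R-deficient libraries in favour of dilution and was withdrawn. Camera with the preset correlation found that the density effect differed between the genotypes in 19 of 47 lists, while 0 genes passed the edgeR test on their own and 0 lists passed with an estimated correlation (lowest adjusted p = 0.524). The median difference, H2R deficient minus wild type on the log2 scale, was positive for MHC class II presentation (1.81), B cell markers (1.47), cytosolic ribosomal proteins (1.17), proliferation (1.13), mitochondrially encoded (1.06) and nuclear-encoded (0.50) oxidative phosphorylation, and inflammatory cytokines and chemokines (0.42). It was negative for T cell (-2.07) and mast cell (-1.53) markers, specific granule proteins (-1.02), mature neutrophil genes (-0.76), gelatinase and secretory vesicle proteins (-0.61), integrins and migration (-0.57), neutrophil ageing and retention (-0.56), glycolysis (-0.50), NADPH oxidase subunits (-0.44), type I interferon-stimulated genes (-0.34), autophagy and mitophagy (-0.27) and apoptosis and survival regulators (-0.26). With total counts only, the medians of the last 2 lists turned positive (0.06 and 0.08). The T cell list summed to 54.1 CPM in H2R-deficient high-density library 2 and to 13.6 to 20.6 CPM in the other 3 high-density libraries, and the cause was not tested. The mast cell list included Hdc, which made up most of its summed level in these neutrophil libraries.

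The first pattern is the rise of B cell, dendritic cell, class II and proliferation transcripts with low density in both genotypes. A lower share of neutrophils that raised every other cell type by the same factor would change B cell and macrophage markers alike if neutrophils expressed neither list. Whether they did was not tested. The lower quartile of B cell marker changes lay above the upper quartile of macrophage marker changes by 1.47 or more on the log2 scale in both genotypes. Only under that condition does this argue against such a like rise. Dividing early neutrophil precursors stay open as a source of the proliferation signal, which summed to at least 349 CPM in low-density libraries, since Mpo, Elane, Ctsg and Ms4a3, chosen after their values were seen, summed to at most 0.610 CPM there, but with Prtn3 added the sum reached 2.22 CPM and passed the bound of 1 CPM in 3 of 4 libraries. B cells in the low-density population and a rise of these transcripts in other cells cannot be told apart, because the finding that 12 of 14 B cell markers were at least 2-fold higher in each genotype only restates the pattern. How the populations were purified and whether a marker was used is not given in the sources used here, and a biological difference in which cells accompany low-density neutrophils in each genotype stays open.

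The second pattern is the drop of neutrophil lists in low-density libraries after TMM scaling. The choice of scaling is argued against as the whole cause for mature neutrophil genes in H2R-deficient libraries, where the median stayed at -0.69 with total counts only and the upper quartile at -0.50. For glycolysis in wild-type libraries the scaling may account for the direction, since the median became 0.15. A single dilution of neutrophil RNA by RNA of other cells would lower mature neutrophil and specific granule genes alike if those cells expressed neither list. Whether they did was not tested. In wild-type libraries the middle ranges of these lists lay apart by 0.20 on the log2 scale, with granule genes higher. Under that condition this argues against dilution as the only cause there. In H2R-deficient libraries the ranges overlapped (a gap of -0.11) but the upper quartile of granule genes lay above 0, at 0.12, so dilution and a change within neutrophils cannot be told apart there.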

How the results depend on the processing

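The absence of scaling factors and the removal of both libraries of a number were chosen after seeing the data, and the other alternatives were fixed before. Subsets of libraries were first run with genes filtered again, and holding the genes of the full fit was decided after those values were seen. No named gene that was called reversed its sign under any alternative run, and for the causes of the changes below, unless stated, the cause was not tested. The wild-type density count of 1888 became 4946 with total counts only, which moved 4822 calls to the higher side, 3361 without the low-count filter, 1221 with at least 10 CPM in 2 libraries, where 7433 genes entered, and 581 when only those groups were fitted (608 with genes filtered again), where 2 residual degrees of freedom remained. The H2R-deficient density count of 8044 became 4499 under the stricter filter. The 31 calls between genotypes at high density became 73 with total counts only, 699 with DESeq2 (290 higher, 409 lower), 2 with limma-voom, 3 with limma-voom and the number as a random effect, 1095 without the filter, 56 under the stricter filter, and 0 with only those groups (0 with genes filtered again). The count of 0 at low density became 915 with DESeq2 and 1360 without the filter. The count of 0 for the difference of effects became 635 with total counts only (622 positive, 13 negative), 990 with DESeq2, 1210 without the filter and 251 under the stricter filter. DESeq2 and the unfiltered fit also made the most false calls in simulated counts. For DESeq2 these were 32, 25 and 18 for genotype at high density, genotype at low density and the difference of effects. These are far fewer than its calls in the data. The simulated counts, with 200 changed genes, therefore cannot show how many of those calls are false. RLE size factors split the wild-type calls into 1179 higher and 879 lower, and DESeq2 into 1292 and 1486, against 1269 and 619.

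Leaving out libraries, with either gene set, singly or both of a number, gave 30 to 1771 calls for wild-type density, 3091 to 8398 for H2R-deficient density, 0 to 40 for genotype at high density, 0 to 121 for genotype at low density and 0 to 3 for the difference. Where an arm kept 1 library, it was assumed to vary like the other groups. The genes kept from the full fit, 1 library at a time, gave 93 to 1771, 5501 to 8398, 0 to 34, 0 to 63 and 0 to 3. With genes filtered again these ranges were 123 to 1724, 5394 to 8341, 0 to 40, 0 to 121 and 0 to 3. The low end of 30 came without both wild-type libraries numbered 2 and that of 3091 without both H2R-deficient libraries numbered 1, and the 121 without wild-type low-density library 2. Among single gene results, the most lost calls were 42 without wild-type low-density library 2 and 41 without wild-type high-density library 2. Camera's calls became 0 in every contrast with an estimated correlation, and fry called 11 lists for wild-type density, 27 for H2R-deficient density, 3 for genotype at high density and 0 for the other 2. The correlation of density effects, 0.785, was 0.876 under the stricter filter and 0.625 to 0.773 with libraries left out, and that of genotype effects, 0.0529, ranged from -0.110 to 0.239.

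The labels number the libraries 1 and 2 in H2R-deficient and 2 and 4 in wild-type groups, and nothing says that a number marks an animal. Low- and high-density libraries with the same number deviated together from their group means, at r = 0.326 in H2R-deficient and 0.155 in wild-type libraries, and because deviations mirror each other in groups of 2, the 4 pairs give only 2 separate values, which does not establish a pairing. With the number as a replicate block edgeR called 2621 genes for wild-type density, 8450 for H2R-deficient density and 28 for the difference (12 positive, 16 negative), and the consensus correlation within a number was 0.0578.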

Other observations

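All tests of explanations in this part were chosen only after the result was seen. Genes named in this part for their level in single libraries were chosen after their values were seen. Ighm counts exceeded Ighd counts by a ratio of 92.6 to 136 in the 4 low-density libraries and of 28.6 to 61.1 in the 4 high-density libraries, while Cr2 and Fcer2a, which follicular B cells express, stayed at 7 to 18 and 6 to 25 counts in the low-density libraries. The B cell list summed to 3239 and 3195 CPM in H2R-deficient and to 1510 and 545 CPM in wild-type low-density libraries, so the wild-type libraries differed from each other more than the H2R-deficient ones did. The dendritic cell list summed to 179 to 654 CPM in low-density and to 8.65 to 20.2 CPM in high-density libraries.

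Xist, which is expressed from the inactive X chromosome of female cells, lay at 71.1 to 226 CPM in high-density and 363 to 626 CPM in low-density libraries, while the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 0 to 4 counts per library. Of the granule proteins of early neutrophil development, Mpo had 0 to 3 and Elane 0 to 4 counts per library, Prtn3 had 6 to 20 in high-density and 12 to 37 in low-density libraries, and the whole primary granule list summed to 306 to 465 CPM. The later granule protein Ltf lay at 105 ± 34.8 CPM in wild-type and 396 ± 164 CPM in H2R-deficient high-density libraries. The chemokine receptor Ccr2 rose with low density in wild-type libraries, from 14.3 ± 5.65 to 47.2 ± 1.43 CPM.

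The third pattern is the lower median of macrophage, monocyte and eosinophil markers, few of which passed on their own, in H2R-deficient than in wild-type high-density libraries. A single wild-type library with more of these cells is argued against, since the median change of the macrophage and eosinophil lists, -1.48 with all libraries, was -1.28 without wild-type high-density library 4 and more negative without library 2. Fewer macrophages, monocytes and eosinophils in the H2R-deficient population and lower expression within neutrophils cannot be told apart, because the finding that 33 of the 37 measured members of the 3 lists were lower only restates the pattern, and the summed monocyte list hardly differed. The count of 31 called genes fell to 0 when only the high-density libraries were fitted, which limits how firmly single genes can be read.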
